A study of Mus musculus with 16 samples.

How the data were processed

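Gene expression was measured in mouse bone-marrow-derived mast cells, which the labels' protocols describe as marrow cells grown for more than 4 weeks with interleukin 3 (5 ng/ml), stem cell factor (40 ng/ml) and 10% serum to a purity above 90%. TIM-3, the product of Havcr2, is a cell-surface receptor of immune cells, and the antibody was a polyclonal goat agonist against it. Cells received the antibody or control goat IgG (15 ug/ml) either while resting or with activation through their IgE receptor, which meant IgE (5 ug/ml) for 1 h and then the antigen DNP-HSA (100 ng/ml). RNA was taken after 2 h or 16 h, isolated on small silica columns and checked for quality and amount, per the labels' protocols. On each of 16 two-colour mouse arrays, RNA of anti-TIM-3-treated cells carried Cy5 and RNA of IgG-treated cells Cy3. The 4 groups (resting or activated cells, 2 h or 16 h) have 4 arrays each. No array exchanged the dyes, so within a group the antibody's effect and a gene's own dye bias cannot be told apart. A dye bias that is equal on all arrays cancels when the ratios of 2 groups are compared. The labels do not say that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

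The deposited scanner files hold spot intensities on a linear scale: per the file headers, Agilent Feature Extraction 9.1.3.1 (version 9 per the submitters' processing notes) read the mean intensity of each spot and the median intensity of its local background in each channel. Its processed intensities were background-subtracted, detrended and dye-normalized with a linear and a lowess step, per the file headers. The log ratio deposited beside them is log10 of processed Cy5 over processed Cy3. It is set to 0 at 25.2% of spots, where neither channel gave a usable processed signal. The labels name version 5.5 of Agilent's dual-color protocol. The authors' deposited value table holds the same log10 ratios (largest difference 0), with every column's median at 0, so its scale and its direction are known.

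The main values were computed from the intensities with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) to read files. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with weight 0 for control and outlier spots. The log2 ratio is Cy5 over Cy3, that is anti-TIM-3 over IgG, and positive values are higher with anti-TIM-3. The offset is large beside the net signal of a typical spot (median Cy3 intensity 61.2 to 78.8 over a background of 29.5 to 34.5), so changes of dim genes are understated. Of 45018 spots per array, 1639 controls were left out and repeated spots of a probe were averaged, which left 41174 probes. A probe was kept if it was well above background in either channel on at least 3 of the 4 arrays of a group (25315 probes). Probes were named through RefSeq accessions (22951 probes), current symbols (6659) or older symbols (3109), and 8455 kept the file's name. Each of the 17032 genes tested is represented by its brightest probe. Of these genes, 5851 had other kept probes, which differed in places and are averaged in an alternative, and 3584 have only a provisional name. Outlier spots took out 595 of 272512 gene values.

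One model of all 16 arrays gave 1 mean per group (lmFit, eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The 11 comparisons were the mean ratio of each group against 0 (4), the differences between groups in that ratio (4), and the effect of IgE and antigen in IgG-treated cells at 2 h, at 16 h and between the times (3). These last use the Cy3 channel alone after Aquantile normalization between arrays and are comparisons across arrays. Where a gene was not well above background on any array of one side, its change is given as a bound ("at least"), against the lowest signal well above background on each array or the gene's own if higher. The anti-TIM-3 response of the genes changed by antigen was described with the antigen calls taken from 2 replicate numbers and the ratios from the other 2, since the comparisons share arrays.

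There were 27 gene lists (501 genes), written from general knowledge: cytokines and growth factors, chemokines, immediate early genes, NF-kappaB targets, STAT5 targets, interferon response, TGF-beta response, granule proteases and mediators, mast cell receptors and transcription factors, Fc-epsilon-RI signalling, eicosanoid synthesis, the TIM family with ligands and inhibitory receptors, apoptosis, cell cycle, unfolded protein response and ATF4 targets, cholesterol synthesis, glycolysis and hypoxia, heat shock and oxidative stress, cytoskeleton and migration, ribosomal proteins, and markers of macrophages and dendritic cells, neutrophils, basophils, eosinophils, lymphocytes, erythroid cells and fibroblasts. Each was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Of 297 list tests 103 passed, and 40 with an estimated correlation. Each comparison names Havcr2, the 10 largest rises and 10 largest falls with the same direction on all 4 arrays (5 and 5, with no overlap between groups, for differences of responses), and up to 4 members per list described. Provisional names were passed over. The lists, tests, rule for names and alternatives were fixed before the data were examined. Settled after first values were seen were the matching of older symbols in the lists and the reading that all 4 arrays must hold a value, which took Lars2, Grn, Fcer1a, Csf2rb and Csf2rb2 out of the largest rises in resting cells at 16 h and brought in Cma1, Rack1, Rps18, Rpl37a and Rpl5.

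The arrays lie on 4 slides, each with arrays of more than 1 group, and slide was fitted as a block and values were also taken within slides. The groups share replicate numbers, taken from the titles. Deviations from the group means, correlated across genes, were alike between arrays of the same number in Cy3. Of 24 pairs 24 were over 0.1 (lowest 0.115, mean 0.37, against -0.12 for different numbers). The numbers thus pair the samples and were fitted as a block in an alternative, not the main fits. In Cy5 21 of 24 pairs passed (mean 0.36) and in the ratios, which were checked first, 12 of 24 (mean 0.12, from -0.45 to 0.64). Other alternatives were Agilent's processed signals, the authors' value table, no background correction, an offset of 16, centring on array medians in place of loess, no filter or a strict filter (20163 probes), the mean of a gene's probes, only the groups compared in the fit, an adjusted p under 0.01, an estimated correlation in camera, each array left out in turn and, for antigen effects, the Cy5 channel, quantile normalization and a separate-channel model. A fit without 3 arrays of resting cells that stood apart was added after the data were seen. With 200 genes shifted in simulated data, 65.7% of shifts of 0.25, 98.5% of 0.5 and 100% of 1 on the log2 scale were recovered for activated cells at 2 h. For the difference between activated and resting cells at 2 h the shares were 38.8%, 86.6% and 100%, and for the antigen effect at 2 h 31.3%, 83.6% and 95.5%.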

Results

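The series asked how an agonist antibody against TIM-3 changes gene expression in mouse mast cells. The 16 arrays compared anti-TIM-3 (Cy5) with IgG (Cy3) in resting and activated cells at 2 h and 16 h, 4 arrays per group. Within a group a rise or fall may be dye bias in part. Between 53.7% and 62.1% of spots were well above background in Cy3 and between 54.8% and 67.7% in Cy5, and 0 spots were saturated. Spike-in ratios followed their nominal values with a correlation of 0.989 to 0.996 and a slope of 0.863 to 0.898 on the log scale. After loess the SD of the log2 ratios over the genes of an array was 0.12 to 0.26. The number of arrays limits the precision. Changes given below are mean log2 ratios of 4 arrays, or of 3 where n = 3 is given, positive where expression was higher with anti-TIM-3. A gene named among the largest rises or falls had the same direction on all 4 arrays. Beside the counts of a gene list, the adjusted p is the list's.

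Havcr2, the gene of the receptor itself, was at 0.04 ± 0.16 (SD, n = 4) in resting cells at 2 h (adjusted p = 0.666). In activated cells at 2 h it rose by 0.59 ± 0.08 (1.51-fold, adjusted p = 6.69e-07). At 16 h it fell to -0.24 ± 0.13 in resting cells (adjusted p = 0.00853) and was at 0.08 in activated cells (adjusted p = 0.292). Under median centring the value in resting cells was 0.33 (adjusted p = 0.000412), above that scaling's median gene at 0.30. The fall did not pass without replicate 1 (-0.22, adjusted p = 0.0551) or replicate 3 (-0.18, adjusted p = 0.079). The response differed between activated and resting cells by 0.55 at 2 h (adjusted p = 0.000327) and by 0.32 at 16 h (adjusted p = 0.0193). The latter was lost without resting replicates 1 (adjusted p = 0.0617) or 3 (0.0731) or activated replicates 2 (0.0576) or 4 (0.0584). Between 16 h and 2 h it differed by -0.51 in activated cells (adjusted p = 0.000244), and the value in resting cells was -0.28 (adjusted p = 0.0982). Antigen itself raised Havcr2 in IgG-treated cells by 1.07 at 2 h (2.1-fold, adjusted p = 1.05e-09). At 16 h the antigen effect was 0.15 (adjusted p = 0.137), and 0.47 between anti-TIM-3-treated cells (Cy5, adjusted p = 0.000132).

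In resting cells, anti-TIM-3 for 2 h raised genes of monocyte-attracting chemokines. Ccl3 rose by 1.29 ± 0.13 (SD, n = 4, 2.44-fold, adjusted p = 3.54e-09) and Ccl2 by 1.13 ± 0.11 (2.19-fold, adjusted p = 3.52e-10). Ccl4 rose by 1.00 ± 0.35 (adjusted p = 4.18e-05) and Ccl7 by 0.90. Egr3 (1.00), an early-response transcription factor, and Aldoa (1.12), a glycolytic aldolase, rose as well. So did the ribosomal protein genes Rpl41 (1.01) and Rps23 (0.97), the ribosome-bound scaffold Rack1 (0.88), and Lrrc58 (1.07). Falls were smaller. Chtf8, a sister-chromatid cohesion factor, fell by 0.62 (adjusted p = 2.72e-05). Cenpb, which binds centromeres, Tmem242, Niban2, Ogfr, Itga2b (the integrin alpha-IIb chain), Sema6b, the Janus kinase Tyk2, Usp5 and Edem2 fell by 0.61 to 0.48. Standard errors of these 20 genes ran from 0.04 (Aldoa) to 0.12 (Ccl4).

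Of 18 chemokines measured in resting cells at 2 h, 7 rose and 0 fell over all genes tested (8 and 0 adjusted over the list alone). Camera gave adjusted p = 1.19e-13 (0.00443 with an estimated correlation). Immediate early genes, induced within minutes of a signal, rose in 14 of 29 and fell in 0 (14 and 1 adjusted over the list alone). Egr3, Nr4a1 (0.80), Egr1 (0.61) and Fos (0.49) led them (list, adjusted p = 4.55e-09). Ribosomal protein genes rose in 20 of 24 and fell in 1 (20 and 1 adjusted over the list alone), Rplp1 and Rps18 (n = 3) by 0.86 each (list, adjusted p = 2.54e-54). Basophil markers rose in 3 of 7 and fell in 0 (4 and 0 adjusted over the list alone), with Ccl3 and the protease gene Mcpt8 (0.33) among them (list, adjusted p = 1.19e-06). Heat shock and oxidative stress genes rose in 4 of 15 and fell in 0 (5 and 0 adjusted over the list alone), the haem oxygenase gene Hmox1 by 0.39 (list, adjusted p = 0.0168).

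Mast cell receptors rose in 6 of 17 genes and fell in 0 in resting cells at 2 h (7 and 1 adjusted over the list alone). Among them were the granule membrane gene Cd63 (0.84), the IgE-binding chain Fcer1a (0.80) and the IL-33 receptor Il1rl1 (0.69). The list had adjusted p = 7.51e-09, and adjusted p = 0.0882 with an estimated correlation. Granule genes rose in 7 of 19 and fell in 1 (8 and 1 adjusted over the list alone), led by the chymase Cma1 (0.66, n = 3), with adjusted p = 0.000751 (adjusted p = 0.217 with an estimated correlation). Cytokines rose in 4 of 25 and fell in 0 (4 and 0 adjusted over the list alone), Il6 by 0.46 and Csf1 by 0.44. Their median was 0.03 (adjusted p = 0.014, and adjusted p = 0.163 with an estimated correlation), and under median centring -0.06 relative to the median gene. Cell cycle genes rose in 0 of 29 and fell in 7 (1 and 8 adjusted over the list alone), the replication helicase gene Mcm6 by 0.27. Under median centring Mcm6 was at 0.32 (adjusted p = 0.000323), above that scaling's median gene at 0.21. Their median was -0.07 (adjusted p = 0.0316, and adjusted p = 0.233 with an estimated correlation), and 0.06 relative to the median gene under median centring. Glycolysis genes rose in 3 of 19, among them Aldoa and Ldha (0.68), and fell in 3, among them Eno1 (-0.46), and 4 rose and 3 fell adjusted over the list alone. That list's adjusted p was 0.000241, and adjusted p = 0.18 with an estimated correlation.

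In all, 2390 of 17031 genes changed in resting cells at 2 h, 1208 higher and 1182 lower. At least 2-fold changes were 7 rises and 0 falls, and the median absolute change of called genes was 0.20. The count was 375 (271 higher and 104 lower) with only this group's arrays in the fit, 1263 without replicate 1 and 2285 with slide as a block. Centring arrays on their median in place of loess moved the median gene to 0.21 here, and to 0.22, 0.30 and 0.39 in activated cells at 2 h, resting cells at 16 h and activated cells at 16 h. The calls in resting cells at 2 h then split into 10144 higher and 320 lower. The cell cycle list was lost without replicate 1 (adjusted p = 0.0925) or 3 (0.0614) and, like the cytokine list, without 3 arrays described below (0.0529). With Agilent's processed signals the granule (0.416), mast cell receptor (0.112), glycolysis (0.206), heat shock (0.416) and cell cycle (0.0865) lists did not pass. With only this group fitted 16 named genes did not pass, among them Itga2b (adjusted p = 0.0861), Tmem242 (0.051), Usp5 (0.0651), Fcer1a (0.0594), Mcm6 (0.0783) and Hmox1 (0.175). With replicate number as a block the TIM family list passed (adjusted p = 0.0482).

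In activated cells, anti-TIM-3 for 2 h raised secreted mediators many-fold over IgG. Ccl4 rose by 3.37 ± 0.19 (SD, n = 4, 10.4-fold, adjusted p = 2.01e-12) and Csf2, which encodes GM-CSF, by 3.33 ± 0.14 (adjusted p = 6.37e-17). Il6 rose 6.50-fold (2.70, adjusted p = 2.4e-15), Ccl3 6.41-fold, Il2 5.45-fold, Tnf 5.42-fold, Ccl2 4.94-fold and Hbegf, an EGF-receptor ligand, 4.91-fold. The orphan nuclear receptor gene Nr4a1 rose 7.01-fold (2.81, adjusted p = 7.08e-15) and Ptgs2, the inducible prostaglandin synthase, 6.12-fold (2.61, adjusted p = 4.03e-14). Falls stayed under 2-fold. The membrane-bound chemokine gene Cx3cl1 fell by 0.76 (adjusted p = 2.68e-09) and Myb, a transcription factor of blood progenitors, by 0.74 (adjusted p = 9.04e-07). The G protein gene Gnaz fell by 0.73 and Kcnn4, a calcium-activated potassium channel, by 0.67. Niban2, Itga2b, Tyk2, Gsdme, Enkur and Klc1 fell by 0.64 to 0.61, and another probe of Klc1 rose. Standard errors of these 20 genes were 0.04 (Il2) to 0.12 (Ccl4).

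Cytokines and growth factors rose in 19 of 25 genes and fell in 1 in activated cells at 2 h (20 and 1 adjusted over the list alone). Their median was 0.70 (adjusted p = 1.27e-132, and 9.16e-05 with an estimated correlation). Chemokines rose in 13 of 18 and fell in 0 (14 and 0 adjusted over the list alone), Ccl7 by 2.10 (list median 0.44, adjusted p = 4.43e-52). Immediate early genes rose in 23 of 29 and fell in 1 (23 and 2 adjusted over the list alone), with a median of 0.56 (adjusted p = 6.21e-37). Egr3 stood at 2.25, the phosphatase gene Dusp2 at 1.87 and Maff at 1.74. NF-kappaB targets rose in 10 of 20 and fell in 3 (11 and 4 adjusted over the list alone, adjusted p = 7.07e-06). Among them were the inhibitor family members Nfkbiz (1.28) and Nfkbid (1.20) and the subunit Rel (0.98). STAT5 targets rose in 7 of 12 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.000187), the survival gene Bcl2l1 by 0.64 and the feedback inhibitor Cish by 0.55. Heat shock and oxidative stress genes rose in 10 of 15 and fell in 0 (12 and 0 adjusted over the list alone), Hspa1a by 0.92 and Hmox1 by 0.67 (list, adjusted p = 1.14e-05). Ribosomal protein genes rose in 21 of 24 and fell in 0 (21 and 0 adjusted over the list alone), Rps18 by 0.89 (list, adjusted p = 6.9e-20). Basophil markers rose in 4 of 7 and fell in 0 (4 and 0 adjusted over the list alone), and Il4, a cytokine of type-2 responses, rose by 2.14 (list, adjusted p = 9.3e-24).

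TGF-beta response genes rose in 6 of 15 and fell in 2 in activated cells at 2 h (7 and 2 adjusted over the list alone), with adjusted p = 0.0164 (adjusted p = 0.256 with an estimated correlation). Granule genes rose in 8 of 19 and fell in 1 (9 and 2 adjusted over the list alone), with adjusted p = 0.00122 (adjusted p = 0.1 with an estimated correlation). Hdc, the histamine-forming enzyme, rose by 0.90. Eicosanoid genes rose in 2 of 10 and fell in 0 (2 and 0 adjusted over the list alone), Ptgs2 and the 5-lipoxygenase gene Alox5 (0.38), with adjusted p = 0.000636 (adjusted p = 0.297 with an estimated correlation). The TIM family with ligands and inhibitory receptors rose in 5 of 13 and fell in 0 (5 and 0 adjusted over the list alone), including Pirb (0.56) and the PD-L1 gene Cd274 (0.43), with adjusted p = 0.0062 (adjusted p = 0.0639 with an estimated correlation). Glycolysis genes rose in 6 of 19 and fell in 3 (6 and 4 adjusted over the list alone), Aldoa by 1.08 and Vegfa by 0.70, with adjusted p = 0.00166 (adjusted p = 0.122 with an estimated correlation). Cell cycle genes fell in 13 of 29 and rose in 4 (4 up and 13 down adjusted over the list alone), with adjusted p = 0.0235 (adjusted p = 0.144 with an estimated correlation). Mcm6 fell by 0.57 and the cycle inhibitor Cdkn1a rose by 0.74.

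In all, 5698 genes changed in activated cells at 2 h, 2920 higher and 2778 lower, and 66 rose and 0 fell at least 2-fold. The split was 2266 higher and 3642 lower with Agilent's processed signals and 10291 and 754 with median centring, and 4358 genes passed with slide as a block. With slide as a block the cell cycle list did not pass (adjusted p = 0.121), and with dim probes left out in both channels the eicosanoid list did not (adjusted p = 0.421).

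The response to anti-TIM-3 differed between activated and resting cells at 2 h in 953 genes, 613 with a higher ratio in activated cells and 340 with a lower one. Csf2 (3.08, adjusted p = 6.55e-14) and Il2 (2.43) were higher in activated cells, but these differences are not exact, as neither gene was well above background in IgG-treated resting cells. Tnf (2.38), Ccl4 (2.37, from 1.00 to 3.37) and Ptgs2 (2.24) were higher too. Lower in activated cells were Hs6st1, a heparan sulfate sulfotransferase (-0.67, adjusted p = 1.35e-05), Enkur (-0.62), Cx3cl1 (-0.62), Myb (-0.55, adjusted p = 0.00333) and Fcer1a (-0.71, adjusted p = 0.0412). Cytokines stood higher in 19 of 25 and lower in 0 (19 and 1 adjusted over the list alone, adjusted p = 4.62e-186), chemokines in 9 of 18 and 0 (11 and 0 adjusted over the list alone, adjusted p = 5.89e-40). Immediate early genes were higher in 17 of 29 and lower in 1 (17 and 2 adjusted over the list alone, adjusted p = 1.56e-29). NF-kappaB targets were higher in 7 of 20 (8 up and 1 down adjusted over the list alone, adjusted p = 1.65e-07) and STAT5 targets in 6 of 12 (8 up and 1 down adjusted over the list alone, adjusted p = 2.13e-07). Unfolded protein response (adjusted p = 0.00542), heat shock (adjusted p = 0.000536) and basophil marker lists (adjusted p = 2.32e-18) stood higher too. Ribosomal protein genes had 0 of 24 members called by limma (adjusted p = 0.52 for the list). Mast cell receptors stood lower, with 0 up and 2 down of 17 (0 and 2 adjusted over the list alone), with adjusted p = 0.0202 (adjusted p = 0.191 with an estimated correlation). Eicosanoid genes stood higher through Ptgs2 alone, with adjusted p = 0.000411 (adjusted p = 0.233 with an estimated correlation).

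Within the 2 slides that hold both groups the median differences at 2 h were 0.58 and 0.63 for cytokines, 0.47 and 0.37 for chemokines, 0.47 in each for immediate early genes and 0.11 and 0.18 for NF-kappaB targets. With slide as a block 949 genes passed. The count was 571 with only these groups fitted and 611 and 576 without activated replicates 2 and 4. The split was 376 higher and 419 lower with Agilent's processed signals and 696 and 116 with median centring. Fcer1a did not pass without resting replicates 1 (adjusted p = 0.0894) or 3 (0.0962) or activated replicates 2 (0.13), 3 (0.0768) or 4 (0.122), nor the mast cell receptor list without resting replicate 3 (0.0516).

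In resting cells at 16 h the largest rises, not separable from dye bias, included ribosomal protein genes and a mast cell chymase gene. Cma1, the chymase gene, rose by 0.94 ± 0.14 (SD, n = 4, 1.92-fold, adjusted p = 1.94e-08). Arpc1b, a subunit of the actin-nucleating Arp2/3 complex, rose by 1.00 (adjusted p = 5.17e-09) and Tmsb4x, the actin-binding thymosin beta 4, by 1.03 (adjusted p = 6.95e-05). Rps23 (1.02), Rack1 (0.94), Rps18 (0.93), Rpl37a (0.92) and Rpl5 (0.86) rose as well. The rises of 2 genes were uneven between arrays. These were Pigt, part of the enzyme that attaches GPI anchors (1.99 ± 0.88, adjusted p = 0.00166), and Ptprz1, a receptor tyrosine phosphatase (1.41, adjusted p = 0.00108). The falls included Anp32a (-1.38 ± 1.16, adjusted p = 0.00809) and Tatdn2 (-1.09 ± 1.03, adjusted p = 0.00915). Mpst (-0.76), Myl10 (-0.69), the splicing factor gene Prpf19 (-0.67), Arhgef1 (-0.65, adjusted p = 0.000187), Raly (-0.64), the cAMP phosphodiesterase Pde4a (-0.60), Ehmt1 (-0.59) and Rab5c (-0.58) fell too. Without replicate 1 or 3, Anp32a (adjusted p = 0.08 and 0.0773), Tatdn2 (0.0911 and 0.0873), Mpst (0.0827 and 0.0857), Myl10 (0.0727 and 0.077), Prpf19 (0.059 and 0.064) and Raly (0.103 and 0.107) did not pass, nor Rab5c without replicate 1 (0.0931).

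Ribosomal protein genes rose in 22 of 24 and fell in 0 in resting cells at 16 h (23 and 1 adjusted over the list alone). Their median was 0.48 (adjusted p = 1.65e-50, and 2.46e-05 with an estimated correlation). Granule genes rose in 10 of 19 and fell in 3 (10 and 3 adjusted over the list alone), among them the serotonin-forming enzyme Tph1 (0.84) and the granzyme Gzmb (0.68, n = 3). They had adjusted p = 4.1e-07, but adjusted p = 0.167 with an estimated correlation. Mast cell receptors rose in 7 of 17 and fell in 0 (8 and 1 adjusted over the list alone), Fcer1a by 1.33 (n = 3), Il1rl1 by 0.83 and Cd63 by 0.66 (n = 3). Their adjusted p was 7.49e-10, and adjusted p = 0.106 with an estimated correlation. The cytokine receptor subunit Csf2rb was at 1.09 (n = 3), and at 0.14 (adjusted p = 0.345) when its probes were averaged. Glycolysis genes rose in 8 of 19 and fell in 2 (8 and 2 adjusted over the list alone), Aldoa by 0.68 (n = 3), with adjusted p = 0.00742 (adjusted p = 0.14 with an estimated correlation). Eicosanoid genes rose in 2 of 10 and fell in 0 (2 and 0 adjusted over the list alone), Alox5 by 0.59, with adjusted p = 0.0352 (adjusted p = 0.41 with an estimated correlation). Cytokines (adjusted p = 0.977), chemokines (0.223) and immediate early genes (0.902) did not pass at this time.

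In all, 3695 genes changed in resting cells at 16 h, 1996 higher and 1699 lower, and 8 rose and 2 fell at least 2-fold. The count was 1452 without replicate 1 and 1452 without replicate 3. Without 3 arrays of resting cells that stood apart (replicate 3 at 2 h and replicates 1 and 3 at 16 h) it was 523 (363 higher and 160 lower). The eicosanoid list (adjusted p = 0.311) and 12 named genes then did not pass, among them Havcr2 (0.311), Tatdn2 (0.744) and Pde4a (0.139), and the chemokine (0.0367), unfolded protein response (0.0367) and basophil (0.0463) lists did. Averaged over these 3 arrays, 28 genes differed by over 2-fold from the median of the other arrays, among them Pigt, Ptprz1, Anp32a and Tatdn2. Tatdn2 was low on the arrays of 16 h (-2.04 and -1.92) but not on replicate 3 at 2 h (0.16). The count was 1729 with only this group fitted, which ended 7 named gene calls and the eicosanoid (0.0562) and glycolysis (0.0663) lists, and 3216 with slide as a block, and the split 11547 and 922 with median centring. The eicosanoid list was lost without replicate 3 (adjusted p = 0.0885), and the eicosanoid (0.135) and glycolysis (0.291) lists with Agilent's processed signals. With replicate number as a block the unfolded protein response list passed (adjusted p = 0.0433).

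In activated cells at 16 h, Penk, the precursor of enkephalin peptides, rose most with anti-TIM-3, by 2.58 ± 0.11 (SD, n = 4, 5.97-fold, adjusted p = 4.2e-12). Plet1, a GPI-anchored surface protein, rose by 2.38 ± 0.37 (5.19-fold, adjusted p = 1.05e-11), Ccdc184 by 2.15 and Igfbp5, an IGF-binding protein, by 2.07. The T-cell-attracting chemokine genes Ccl17 (1.81, 3.51-fold, adjusted p = 1.24e-10) and Ccl1 (1.64, 3.12-fold, adjusted p = 7.53e-09) rose too, as did Prss12 (1.66), Wnt9a (1.49), the T-box factor Eomes (1.42) and Snap47 (1.42). Tgfbi, an extracellular matrix protein, fell to -1.17 ± 0.34 (adjusted p = 8.43e-08), Clec7a, the beta-glucan receptor, to -1.02 (adjusted p = 5.58e-09), and Cd14, the endotoxin co-receptor, to -0.91 (adjusted p = 1.49e-07). Rsad2, an antiviral enzyme, fell by 0.84 (adjusted p = 2.59e-07). Emp1 (-1.07), haptoglobin (Hp, -1.03), Emb (-0.97), the serotonin transporter gene Slc6a4 (-0.86), Gstm1 (-0.86) and Ctsl (-0.84) also fell. Standard errors of these 20 genes were 0.04 (Snap47) to 0.11 (Ccl1).

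Interferon response genes fell in 16 of 25 and rose in 0 in activated cells at 16 h (0 up and 18 down adjusted over the list alone). Their median was -0.29 (adjusted p = 5.35e-11, and 0.0477 with an estimated correlation), with Rsad2, Ifit1 (-0.74), Ifit3 (-0.71) and the transcription factor gene Irf7 (-0.71) lowest. Macrophage and dendritic cell markers fell in 11 of 17 and rose in 2 (2 up and 11 down adjusted over the list alone). They included Cd14, the IgG receptor gene Fcgr1 (-0.78) and lysozyme (Lyz2, -0.70), with a median of -0.36, adjusted p = 1.23e-07, and adjusted p = 0.116 with an estimated correlation. Cell cycle genes rose in 19 of 29 and fell in 2 (20 and 2 adjusted over the list alone). Pcna (0.50), E2f1 (0.49) and Rrm2 (0.48) were highest (list median 0.31, adjusted p = 3.18e-08, and 0.0193 with an estimated correlation). Chemokines rose in 11 of 18 and fell in 1 (11 and 2 adjusted over the list alone), Ccl24 by 1.30 (list, adjusted p = 3.16e-05, and 0.0477 with an estimated correlation). Ribosomal protein genes rose in 20 of 24 and fell in 0 (22 and 2 adjusted over the list alone), Rplp1 by 1.14 (list median 0.41, adjusted p = 1.92e-19). Immediate early genes fell in 12 of 29, Egr3 by 0.74 and Ier2 by 0.70, and rose in 3, Dusp4 by 0.82 (3 up and 13 down adjusted over the list alone). Their adjusted p was 0.000612 (adjusted p = 0.204 with an estimated correlation), and under median centring they stood at 0.01 relative to the median gene (adjusted p = 0.408).

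Eicosanoid genes rose in 4 of 10 and fell in 1 in activated cells at 16 h (5 and 1 adjusted over the list alone), Alox5 by 0.71 (n = 3) and the leukotriene C4 synthase gene Ltc4s by 0.48. Their adjusted p was 0.000612, and adjusted p = 0.282 with an estimated correlation. Glycolysis genes rose in 5 of 19 and fell in 0 (6 and 0 adjusted over the list alone), Ldha by 0.81, with adjusted p = 0.021 (adjusted p = 0.297 with an estimated correlation). Neutrophil markers fell in 2 of 7 and rose in 0 (0 up and 2 down adjusted over the list alone), Mmp8 by 0.76 and Mpo by 0.60, with adjusted p = 0.021 (adjusted p = 0.204 with an estimated correlation). Mast cell receptors rose in 8 of 17 and fell in 4 (9 and 4 adjusted over the list alone), Il1rl1 by 0.89 and Fcer1a by 0.86, with adjusted p = 0.0299 (adjusted p = 0.39 with an estimated correlation). Relative to all genes that list's median went from 0.10 to -0.01 with Agilent's processed signals. It did not pass without replicate 3 (adjusted p = 0.127) or with replicate number as a block (0.0553). Cytokines did not pass as a list (8 up and 4 down of 25, adjusted p = 0.267), with Il1b at 0.83 and Tnf at -0.53, nor did granule genes (11 up and 5 down of 19, adjusted p = 0.14). Cytoskeleton genes (4 up and 7 down of 21, adjusted p = 0.0525) passed with replicate number as a block (0.0442).

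In all, 5144 genes changed in activated cells at 16 h, 2882 higher and 2262 lower, and 30 rose and 4 fell at least 2-fold. With slide as a block 4569 passed. The split was 2334 and 2449 with Agilent's processed signals and 12070 and 1447 with median centring. Under that centring the chemokine (adjusted p = 0.324) and eicosanoid (0.0538) lists did not pass, nor the glycolysis list with the processed signals (0.217). Relative to the median gene, interferon (-0.27), macrophage (-0.33) and cell cycle (0.45) medians had the same direction under it.

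**Figure D1:**
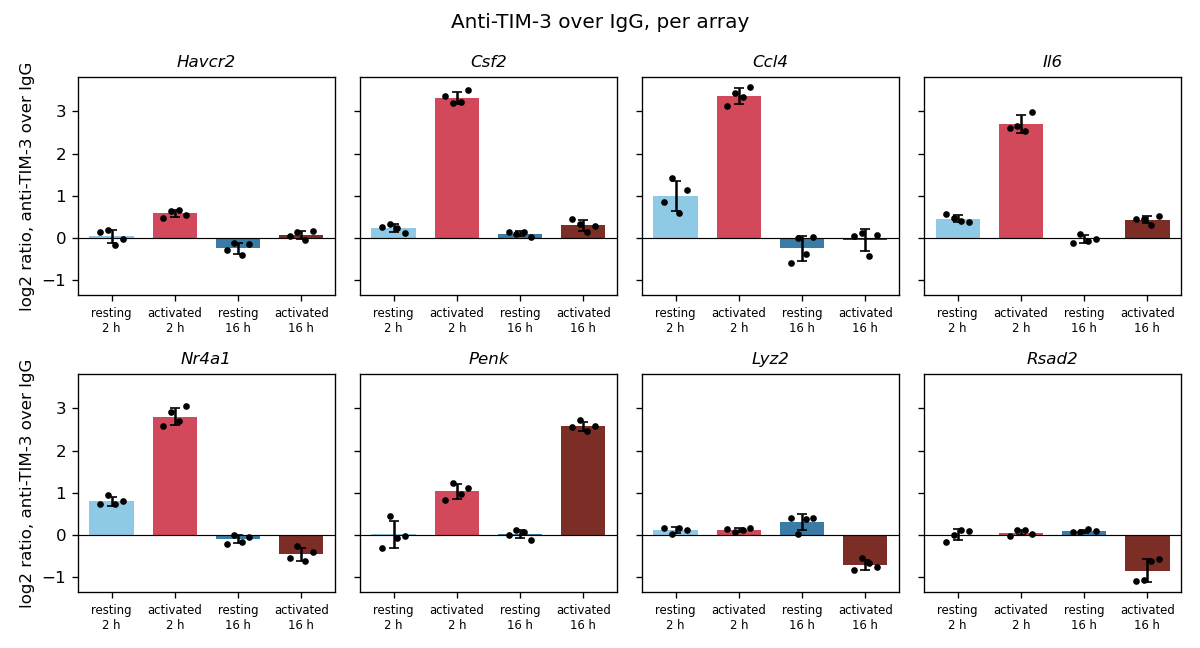
Log2 ratio of anti-TIM-3 over IgG per array (dots) for Havcr2, Csf2, Ccl4, Il6, Nr4a1, Penk, Lyz2 and Rsad2 in the 4 groups, with bars for the mean and error bars for the SD of 4 arrays. Csf2 and Ccl4 stand at 3.33 and 3.37 in activated cells at 2 h and Penk at 2.58 in activated cells at 16 h.

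At 16 h the response differed between activated and resting cells in 1468 genes, 805 higher in activated cells and 663 lower. Penk was at 2.58 in activated and 0.02 in resting cells (difference 2.56, SE 0.12, adjusted p = 1.66e-09), and Plet1 (2.45), Igfbp5 (1.82) and Ccl17 (1.77) followed. Ccdc184 (2.12) was not well above background in resting cells, so its difference is not exact. Lyz2 was at -0.70 in activated and 0.31 in resting cells (difference -1.01, SE 0.08, adjusted p = 3.02e-07), and Hp (-1.16), Tgfbi (-1.15), Clec7a (-0.98) and Emp1 (-0.93) were lower too. Interferon response genes were lower in 15 of 25 and higher in 0 (0 up and 19 down adjusted over the list alone), with a median difference of -0.38 (adjusted p = 1.39e-17, and 0.0385 with an estimated correlation). Macrophage markers were lower in 7 of 17 and higher in 2 (2 up and 10 down adjusted over the list alone), Cd14 by -0.83, with adjusted p = 2.92e-07 (adjusted p = 0.116 with an estimated correlation). Cell cycle genes were higher in 10 of 29 and lower in 0 (14 and 1 adjusted over the list alone), Ccne2 by 0.72, with adjusted p = 1.56e-05 (adjusted p = 0.0504 with an estimated correlation). NF-kappaB targets were higher (adjusted p = 0.0158, and adjusted p = 0.0811 with an estimated correlation), as were chemokines (adjusted p = 0.00138, and adjusted p = 0.117 with an estimated correlation). Immediate early genes were lower, Ier2 by -0.92 and Egr1 by -0.79 (n = 3 in activated cells; list, adjusted p = 2.48e-05, and adjusted p = 0.116 with an estimated correlation). So were mast cell receptors (adjusted p = 0.0146, and adjusted p = 0.201 with an estimated correlation) and Fc-epsilon-RI signalling genes, Rasgrp4 by -0.53 (list, adjusted p = 0.0383, and adjusted p = 0.215 with an estimated correlation).

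Within the 2 slides that hold both groups the median differences at 16 h were -0.33 and -0.47 for interferon, -0.35 and -0.23 for macrophage, 0.17 and 0.15 for cell cycle and -0.14 and -0.15 for immediate early genes. With slide as a block 1159 genes passed. The count was 908 and 926 without resting replicates 1 and 3, 862 without activated replicate 1 and 641 without the 3 arrays, and the split 1878 and 336 with median centring. Without the 3 arrays the NF-kappaB (adjusted p = 0.0524), mast cell receptor (0.099) and Fc-epsilon-RI (0.16) lists and 14 named genes did not pass, among them Havcr2 (0.158), Ifit3 (0.0511) and Irf7 (0.0925). The Fc-epsilon-RI list was lost without resting replicate 3 (adjusted p = 0.0996) or activated replicates 2 (0.0829) or 4 (0.0557) and with slide as a block (0.0504). With Agilent's processed signals it and the mast cell receptor list were lost (both 0.0688). With replicate number as a block the unfolded protein response (0.0344), cytoskeleton (0.0408) and neutrophil (0.0262) lists passed.

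Between 2 h and 16 h the response of resting cells changed in 49 genes, 15 higher and 34 lower at 16 h. Egr3 went from 1.00 to -0.26 (difference -1.26, adjusted p = 0.000141) and Ccl3 from 1.29 to 0.04 (-1.24, adjusted p = 9.07e-06). Ccl4 (-1.24, adjusted p = 0.00384), Nr4a1 (-0.90, adjusted p = 0.000192) and the ferritin light chain gene Ftl1 (-0.70, adjusted p = 0.00597) were lower too. Higher at 16 h were Fam110b (0.58, adjusted p = 0.0498), the microtubule regulator Stmn1 (0.57, adjusted p = 0.00597), the prion protein gene Prnp (0.51, adjusted p = 0.0199), Mettl7a1 (0.50, adjusted p = 0.0316) and Serpina3g (0.47, adjusted p = 0.00479). Chemokines were lower in 4 of 18 (0 up and 6 down adjusted over the list alone, adjusted p = 1.24e-07, and 0.0382 with an estimated correlation). Immediate early genes were lower in 3 of 29 (0 up and 8 down adjusted over the list alone, adjusted p = 2.56e-07, and adjusted p = 0.0762 with an estimated correlation). Cell cycle genes were higher in 3 of 29 (13 up and 2 down adjusted over the list alone, adjusted p = 2.93e-05, and adjusted p = 0.073 with an estimated correlation). Cytokines (adjusted p = 0.0333, and adjusted p = 0.382 with an estimated correlation) and NF-kappaB targets (adjusted p = 0.00879, and adjusted p = 0.073 with an estimated correlation) were lower as lists. The interferon list was higher (median 0.11, adjusted p = 0.00879, and adjusted p = 0.397 with an estimated correlation). Basophil markers had a median of 0.01, but a mean of -0.16 and a downward test (adjusted p = 0.0358, and adjusted p = 0.493 with an estimated correlation).

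This count of 49 rested on single arrays. It was 25 and 1959 without replicates 1 and 3 at 2 h, and 23, 316, 24 and 634 without replicates 1, 2, 3 and 4 at 16 h. It was 7 without the 3 arrays (13 named genes and the interferon list lost, 0.0792), 8 with only these groups fitted (12 named genes lost), 29 with slide as a block and 275 (128 and 147) with replicate number as a block. The split was 2 and 17 with Agilent's processed signals, 222 and 80 with median centring and 7 and 28 with an offset of 16, and 3821 genes had an unadjusted p under 0.05. Within the 3 slides that hold both groups the median differences were -0.04, -0.10 and -0.21 for chemokines and 0.10, 0.20 and 0.13 for cell cycle genes. Fam110b, Prnp and Mettl7a1 did not pass without replicate 1 at 2 h (adjusted p = 0.151, 0.0988 and 0.139) or replicates 1 (0.216, 0.0867 and 0.162) and 3 (0.189, 0.0762 and 0.0972) at 16 h. Fam110b and Prnp did not pass without replicates 2 (0.0899 and 0.0669) and 4 (0.0642 and 0.0541) at 2 h either. The cytokine and basophil lists were lost without replicate 3 at 2 h (0.193 and 0.201) or replicates 2 (0.139 and 0.15) or 4 (0.111 for both) at 16 h. The basophil list was also lost without replicates 2 (0.0502) or 4 (0.0889) at 2 h. With replicate number as a block the heat shock list passed (0.0464).

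In activated cells the response changed between 2 h and 16 h in 2938 genes, 1562 higher and 1376 lower at 16 h, with 18 at least 2-fold higher and 61 at least 2-fold lower. Ccl4 went from 3.37 to -0.04 (difference -3.42, adjusted p = 4.14e-10) and Csf2 from 3.33 to 0.31 (-3.02, adjusted p = 9.29e-14). Nr4a1 went from 2.81 to -0.45, Egr3 from 2.25 to -0.74 and Tnf from 2.44 to -0.53. Higher at 16 h were Plet1 (2.65, adjusted p = 1.34e-10), Ccdc184 (2.06), Igfbp5 (1.93), Penk (1.53, from 1.04 to 2.58) and Prss12 (1.48). Cytokines were lower in 17 of 25 and higher in 0 (1 up and 18 down adjusted over the list alone, adjusted p = 1.08e-108). Immediate early genes were lower in 22 of 29 and higher in 0 (0 up and 25 down adjusted over the list alone, adjusted p = 1.21e-52), and chemokines lower in 9 of 18 and higher in 3 (4 up and 11 down adjusted over the list alone, adjusted p = 2.89e-26). NF-kappaB (adjusted p = 0.000332), STAT5 (adjusted p = 0.000921), basophil (adjusted p = 1.83e-22) and heat shock lists (adjusted p = 0.00141) were lower too. Interferon response genes were lower in 12 of 25 and higher in 0 (1 up and 15 down adjusted over the list alone, adjusted p = 1e-08), Rsad2 by -0.90. Cell cycle genes were higher in 21 of 29 and lower in 4 (23 and 4 adjusted over the list alone, adjusted p = 1.2e-12), Mcm6 by 0.72. These list calls held with an estimated correlation.

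Macrophage markers were lower at 16 h than at 2 h in 10 of 17 and higher in 2 (2 up and 10 down adjusted over the list alone), with adjusted p = 0.000154 (adjusted p = 0.0902 with an estimated correlation). Neutrophil markers (adjusted p = 0.0353, and adjusted p = 0.0902 with an estimated correlation) and cytoskeleton genes (adjusted p = 0.0305, and adjusted p = 0.0811 with an estimated correlation) were lower as lists, the matrix protein gene Spp1 by -1.60. TGF-beta response genes had a median of 0.03, but a mean of -0.26 and a downward test (adjusted p = 0.00898, and adjusted p = 0.154 with an estimated correlation). On the slide that holds both groups the median differences were -0.62 for cytokines, -0.24 for chemokines, -0.61 for immediate early, -0.30 for interferon, 0.32 for cell cycle and -0.27 for macrophage genes, and 1965 genes passed with slide as a block. The cytoskeleton list was lost without replicate 1 at 2 h (adjusted p = 0.0525), with slide (0.112) or with replicate number (0.0539) as a block, and the neutrophil list without replicates 2 (0.0545) or 4 (0.0552) at 2 h. Median centring split the calls into 4228 higher and 1115 lower, and the STAT5 list did not pass under it (adjusted p = 0.0819).

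**Figure D2:**
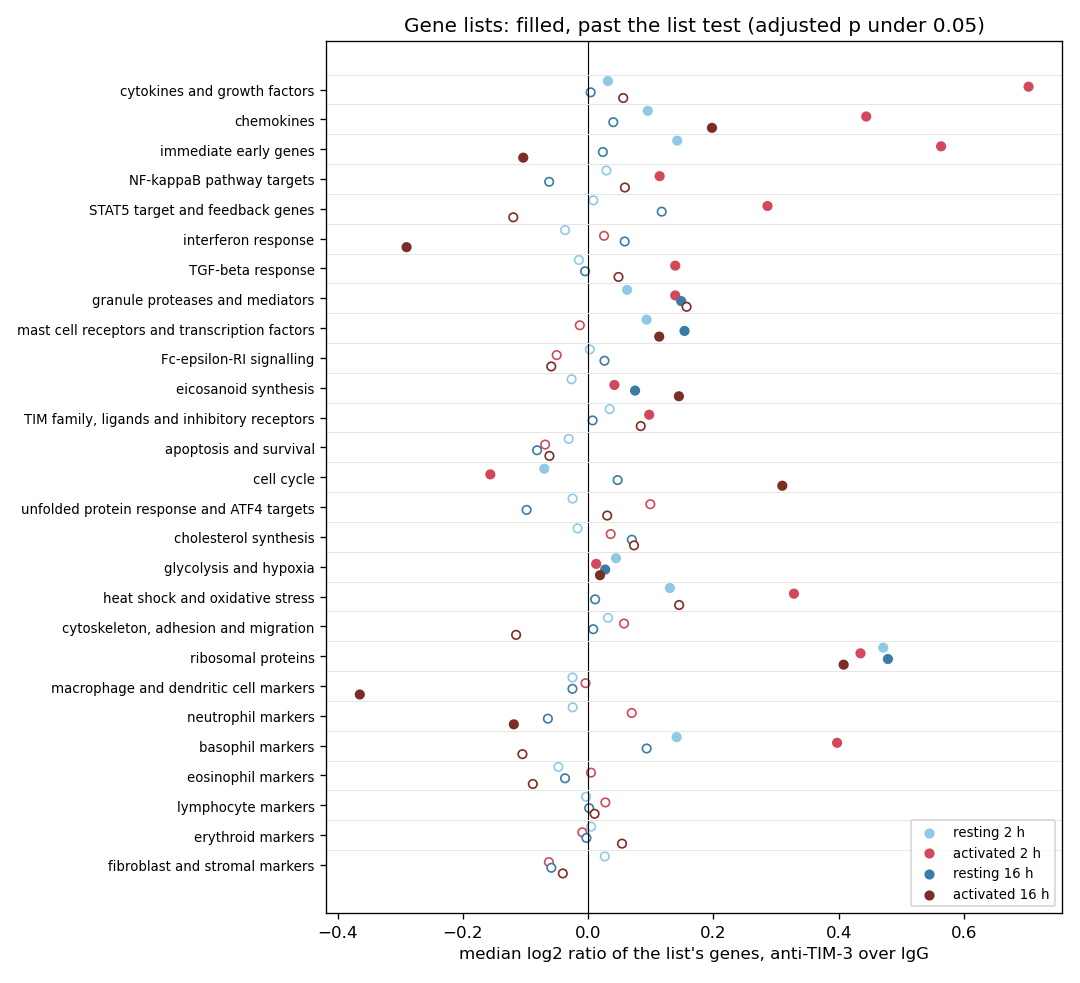
Median log2 ratio of anti-TIM-3 over IgG of the 27 gene lists in the 4 groups, filled where the list passed camera at an adjusted p under 0.05. Cytokines lie at 0.70 in activated cells at 2 h, and interferon response and macrophage genes at -0.29 and -0.36 in activated cells at 16 h.

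Across groups, 385 genes were higher and 285 lower with anti-TIM-3 in all 4 groups, where independent calls would share 4.11 and 2.55. At 2 h, resting and activated cells shared 847 higher and 855 lower genes (207 and 193 if independent), and at 16 h 993 and 840 (338 and 226). The 4 groups share no arrays, but all carry the same dye orientation.

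In IgG-treated cells, where the Cy3 channel shows the effect of IgE and antigen without anti-TIM-3, Ccl1 rose most at 2 h. Its log2 level went from 8.33 ± 0.157 (SD, n = 4) in resting to 13.92 ± 0.253 in activated cells (48.2-fold, adjusted p = 3.43e-15). Crtam, an adhesion receptor of lymphocytes, rose 35.5-fold (adjusted p = 8.17e-16), Rgs16, a G protein regulator, 15.5-fold, and Csf2, not well above background in resting cells, at least 14.7-fold (adjusted p = 1.2e-14). Sphk1, which makes sphingosine 1-phosphate, rose 13.2-fold, and C5ar2 (3.71), Olr1 (3.51), Fst (3.38), Gpd1 (3.27) and the phosphatase gene Ptpn22 (3.25) followed. Il15 fell to -2.25 (4.77-fold, adjusted p = 1.06e-12). Depdc1b (-2.10), Mns1 (-2.04), the ETS factor gene Erg (-1.82), Shisa2 (-1.79), Rwdd3 (-1.77), the mast cell adaptor gene Clnk (-1.76), Fbxo31 (-1.76), Pik3ip1 (-1.74) and Map11 (-1.70) fell too. Standard errors of these 20 genes were 0.05 (Pik3ip1) to 0.27 (Sphk1).

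Antigen raised 20 of 25 cytokines and lowered 2 at 2 h (20 and 2 adjusted over the list alone), Il2 at least 7.16-fold, Hbegf by 2.24 and Il3 by 2.05. Their median was 0.93 (adjusted p = 4.08e-28, and 9.84e-05 with an estimated correlation). Chemokines rose in 10 of 18 and fell in 1 (10 and 1 adjusted over the list alone), Ccl7 by 2.51, with adjusted p = 4.67e-09 (adjusted p = 0.264 with an estimated correlation). NF-kappaB targets rose in 15 of 20 and fell in 1 (15 and 1 adjusted over the list alone), Gadd45b by 2.97, with adjusted p = 2.19e-12 (adjusted p = 0.118 with an estimated correlation). Immediate early genes rose in 15 of 29 and fell in 6 (15 and 6 adjusted over the list alone), Egr3 by 2.73, with adjusted p = 1.04e-06 (adjusted p = 0.123 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 18 and fell in 2 (12 and 2 adjusted over the list alone), Cyp51 by 1.34, with adjusted p = 6.26e-09 (adjusted p = 0.19 with an estimated correlation). Cell cycle genes fell in 25 of 29 and rose in 3 (3 up and 25 down adjusted over the list alone), Mcm7 to -1.50, Plk1 to -1.34 and Mki67 to -1.17. Their adjusted p was 2.19e-12, and adjusted p = 0.118 with an estimated correlation. Heat shock genes rose, Srxn1 by 1.35 (list, adjusted p = 0.0203, and adjusted p = 0.219 with an estimated correlation). Erythroid markers rose in 2 of 6 and fell in 1 (2 and 1 adjusted over the list alone), with adjusted p = 0.0016 (adjusted p = 0.387 with an estimated correlation). TGF-beta response genes (adjusted p = 0.0438, and adjusted p = 0.242 with an estimated correlation) and the TIM family list (adjusted p = 0.0322, and adjusted p = 0.264 with an estimated correlation) rose as well.

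Antigen changed 7290 genes at 2 h, 2740 higher and 4550 lower, 372 and 163 of them at least 2-fold, and 7591 passed with slide as a block. Within the 2 slides that hold both groups the median changes were 0.79 and 1.00 for cytokines, 0.60 and 1.09 for chemokines, 0.15 and 0.55 for immediate early genes, -0.82 and -0.81 for cell cycle genes, and 0.66 in each for cholesterol synthesis. The TGF-beta list was lost without resting replicates 2 (adjusted p = 0.0555) or 3 (0.0521) or activated replicate 4 (0.0566) and with replicate number as a block (0.0728), and the TIM family list without resting replicate 2 (0.0651).

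At 16 h the antigen effect in IgG-treated cells was led by Tnfrsf9, the costimulatory receptor 4-1BB (2.67, 6.38-fold, SE 0.11, adjusted p = 5.78e-10), and Penk (2.61, 6.1-fold, adjusted p = 1.58e-06). Fxyd6 (2.37), the apolipoprotein gene Apoc2 (2.22), the activin A chain Inhba (2.08, SE 0.45, adjusted p = 0.00546), the glutathione transferase genes Gsta1 (2.03) and Gsta2 (1.89), Prss23 (1.99), Kcnd2 (1.78) and Crisp1 (1.68) also rose. Chac1, a glutathione-degrading enzyme, fell to -1.43 (adjusted p = 0.002). Gas6 (-1.12), Pigz (-1.08), Rapgef3 (-1.02), Cyp4a12a (-0.98), Mrvi1 (-0.95), Nupr1 (-0.94), the amino acid transporter gene Slc1a4 (-0.89), Cx3cr1 (-0.86) and Mki67 (-0.83, adjusted p = 1.06e-05) fell too. Cell cycle genes fell in 23 of 29 and rose in 0 (0 up and 23 down adjusted over the list alone), with a median of -0.51 (adjusted p = 1.08e-25, and 0.0234 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 18 and fell in 0 (15 and 0 adjusted over the list alone), Mvd by 0.76, with adjusted p = 4.92e-17 (adjusted p = 0.0616 with an estimated correlation). Chemokines rose in 7 of 18 and fell in 0 (8 and 0 adjusted over the list alone), Ccl17 by 1.57, with adjusted p = 5.97e-05 (adjusted p = 0.278 with an estimated correlation). NF-kappaB targets rose, Tnfaip3 by 0.67 (list, adjusted p = 5.97e-05, and adjusted p = 0.264 with an estimated correlation). ATF4 and unfolded protein response genes fell in 7 of 17 and rose in 0 (1 up and 8 down adjusted over the list alone), Asns to -0.77, with adjusted p = 0.00166 (adjusted p = 0.0616 with an estimated correlation). TGF-beta response genes (adjusted p = 0.0169, and adjusted p = 0.264 with an estimated correlation) and cytokines (adjusted p = 0.0445, and adjusted p = 0.113 with an estimated correlation) rose, Il1b by 1.48. Glycolysis genes fell, Pfkl to -0.32 (list, adjusted p = 0.0482, and adjusted p = 0.242 with an estimated correlation).

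In all, 2123 genes changed with antigen at 16 h, 882 higher and 1241 lower, 35 and 4 of them at least 2-fold. The count was 2116 with slide as a block, 1234 without the 3 arrays and 3288 between anti-TIM-3-treated cells (Cy5). Within the 2 slides that hold both groups the median changes were -0.48 and -0.43 for cell cycle genes, 0.30 and 0.38 for cholesterol synthesis, 0.31 and 0.10 for NF-kappaB targets and 0.59 and 0.00 for chemokines. The cytokine list was lost without resting replicates 3 (adjusted p = 0.0777) or 4 (0.0749) or activated replicates 1 (0.0536) or 3 (0.0533). The glycolysis list was lost without resting replicates 1 (0.0728) or 4 (0.0669) or activated replicates 2 (0.0515) or 3 (0.121) and with slide as a block (0.086). Between anti-TIM-3-treated cells (Cy5) the cytokine (0.0735), TGF-beta (0.0691), unfolded protein response (0.128) and glycolysis (0.138) lists did not pass. With replicate number as a block the immediate early (0.0143) and interferon (0.00264) lists did.

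The antigen effect itself differed between 16 h and 2 h in 5637 genes, 3349 higher and 2288 lower at 16 h. Crtam (-4.95, adjusted p = 3.09e-13), Ccl1 (-4.71), Rgs16 (-3.69) and Egr3 (-3.54) were lower, as was Csf2 (-3.71, not exact, since it was not well above background in resting cells), and Havcr2 was lower by -0.92 (adjusted p = 8.78e-07). Fhdc1 (2.49), Kcnd2 (2.37), Il15 (2.34), Depdc1b (2.17) and Apoc2 (2.16) were higher. Cytokines were lower in 16 of 25 and higher in 2 (2 up and 16 down adjusted over the list alone), with a median of -0.51 (adjusted p = 6.02e-23, and 0.000255 with an estimated correlation). NF-kappaB (adjusted p = 7.09e-07), immediate early (adjusted p = 0.000104) and heat shock genes (adjusted p = 0.0105) were lower, each with adjusted p = 0.299 with an estimated correlation. Chemokines (adjusted p = 0.000136, and adjusted p = 0.673 with an estimated correlation) and erythroid markers (adjusted p = 0.0131, and adjusted p = 0.515 with an estimated correlation) were lower too. Cell cycle genes were higher (adjusted p = 0.0245) and cholesterol synthesis genes lower (adjusted p = 0.0322), each with adjusted p = 0.617 with an estimated correlation. With slide as a block 5957 genes passed, and no slide holds all 4 groups. The cell cycle list was lost without resting replicate 1 at 2 h (adjusted p = 0.0745). The cholesterol list was lost without resting replicates 1 (0.123) or 4 (0.0509) or activated replicates 1 (0.0558) or 2 (0.0591) at 2 h, and without resting replicate 2 (0.0656) or activated replicates 3 (0.0517) or 4 (0.0585) at 16 h. With replicate number as a block the unfolded protein response list passed (0.0326).

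Genes that antigen raised at 2 h had a positive median ratio with anti-TIM-3 in activated cells, and those it lowered a negative one. With antigen calls from replicates 1 and 2 and ratios from replicates 3 and 4, the 1553 raised genes had a median log2 ratio of 0.14 (SD between arrays 0.0219), and 73.1% were above 0. The 2494 lowered genes had a median of -0.10 (SD 0.00924), and 23.9% were above 0. In resting cells the same genes had medians of 0.04 and -0.04. With the replicates exchanged the medians in activated cells were 0.12 (2026 genes) and -0.10 (3365 genes). At 16 h both classes lay above 0. Genes raised by antigen had medians of 0.09 and 0.11 (93 and 251 genes, resting 0.02 and 0.01) and genes lowered by it 0.15 in each set (80 and 354 genes, resting 0.04 and 0.00). Under median centring the genes lowered at 2 h were at 0.17 and 0.19, below that scaling's median gene at 0.22. These medians carry no test.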

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

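The tests of a common response, of slide and culture for the 3 arrays, and of dye bias and macrophages for activated cells at 16 h were chosen only after the result was seen. So were the sampling error required of the brightness test, the choice of genes and arrays in the slide and culture tests, and the restriction to macrophage markers well above background on all 16 arrays.

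The first pattern is the set of 670 genes, most ribosomal protein genes among them, that changed in the same direction in all 4 groups. Dye bias of single probes may account for it in part: 66.3% of 359 other probes of these genes shared the direction, against 60.3% of 6124 probes of genes outside the set and 88.9% of 388 probes of the genes whose response differed at 2 h. So may brightness-tied dye bias. Matched genes of other classes (210, mean brightness 15.3) had a median log2 ratio of 0.22 (bootstrap SE 0.0299), the brighter ribosomal genes (15.8) 0.45. A common response to the antibody stays open, with a median difference of the ribosomal genes between groups compared of at most 0.0494. Without a dye exchange these cannot be told apart.

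The second pattern is 28 genes that stood over 2-fold apart, 21 higher and 7 lower, on replicate 3 at 2 h and replicates 1 and 3 at 16 h of resting cells. Slide stays open: genes chosen in resting cells showed -5.85% of the difference between activated cells at 2 h on different slides, which covers 1 of the 3 slides. A culture shared by replicate number stays open, with 18.3% on the 4 activated arrays of those numbers (37.6% at 2 h and 0.0027% at 16 h) and 46.1% on the other resting array of those numbers. RNA of the IgG-treated samples of these arrays stays open as well, with 59.3% of the difference in Cy3 (from -25.7% to 226% over the genes). No biological explanation was tested.

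The third pattern is the fall of interferon response and macrophage genes in activated cells at 16 h. The tables argue against a dye bias equal on all arrays, since the genes of the list with the smaller difference lay a median of -0.28 from resting cells at 16 h. Fewer macrophages in the anti-TIM-3-treated samples could account for the markers: of 14 measured well on all arrays 10 were lower, among them Lyz2 (-0.70), Cd68 (-0.53), Csf1r (-0.55) and H2-Aa (-0.41), and 1 was higher, Itgax (0.49), while H2-Ab1 (-0.06), Cd74 (0.17) and C1qb (-0.01) were not called. Under median centring Lyz2 was at 0.14, below that scaling's median gene at 0.39. A response of the mast cells to antibody and antigen stays open, as an untested hypothesis.

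Other splits of the same arrays were counted for every comparison. For the 4 groups alone, turning the signs of ratios gives 8 splits, too few for a share under 0.05, with 1 split as large in each, the real one: resting 2 h 2390 genes (highest other 296), activated 2 h 5698 (7), resting 16 h 3695 (17) and activated 16 h 5144 (11). With arrays split freely, 1 of 35 splits, the real one, was as large for the differences at 2 h (953, highest other 1), at 16 h (1468, 0) and over time in activated cells (2938, 0). The same held for antigen at 2 h (7290, 2) and 16 h (2123, 1). These free splits ignore the pairing by replicate number, so they cannot exclude chance by themselves. For antigen between the times (5637) the draws cannot decide, since shuffling all 16 arrays also breaks up the separate effects of time and of antigen. Of 100 splits, the real one among them, 3 were as large (highest other 7025). The 11 draws with all 4 activated arrays of 2 h on one side gave 0 to 7025 genes. Chance cannot be excluded for the difference over time in resting cells (49), where 3 of 35 splits were as large. Its highest other, 2783 genes, set replicates 1, 3 and 4 at 16 h with replicate 3 at 2 h and so points to a structure of the arrays. It is no split by slide. The numbers pair the arrays, and among the 8 splits of each comparison of 8 arrays that part all 4 pairs, the real one was the largest (highest other 1). These 8 are too few for a share under 0.05, so the splits that keep the pairing do not exclude chance. The 2 larger splits of resting cells over time parted fewer pairs.

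Responses also differed between groups by tests of the difference. At 2 h the median gap between activated and resting cells was 0.51 for cytokines, 0.39 for chemokines, 0.41 for immediate early genes, 0.0706 for NF-kappaB targets, 0.38 for STAT5 targets, 0.13 for the unfolded protein response, 0.17 for heat shock genes and 0.21 for basophil markers, and at 16 h -0.38 for interferon response. Between 16 h and 2 h it was -0.0814 for chemokines in resting cells. In activated cells it was -0.64 for cytokines, -0.34 for chemokines, -0.65 for immediate early genes, -0.0754 for NF-kappaB targets, -0.18 for STAT5 targets (not past the threshold under median centring), -0.35 for interferon response, 0.42 for cell cycle, -0.18 for heat shock and -0.25 for basophil markers. The antigen effect on cytokines differed by -0.51 between the times. Havcr2 responses differed by 0.55 and 0.32 between cell states at 2 h and 16 h (the latter not past the threshold without any of 4 single arrays, or without the 3 arrays) and by -0.51 over time in activated cells, and its antigen effect by -0.92.

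In 15 of 297 groups of 4 arrays, 13 of 242 for named genes, a single array lay far from the others, and chance gives about 1 in 20. The gap to the nearest array, over the whole range, was 0.943 for Egr3 and 0.9001 for Ptpn22 (Cy3, activated 2 h), 0.879 for Cx3cr1 and 0.902 for Mrvi1 (Cy3, activated 16 h), 0.906 for Mki67 (Cy3, resting 16 h) and 0.837 for Shisa2 (Cy3, resting 2 h). For log2 ratios it was 0.896 for Ccl4, 0.903 for Clec7a and 0.947 for Plet1 in activated cells at 16 h, 0.846 for Plet1 in activated cells at 2 h, 0.928 for Igfbp5 and 0.923 for Lyz2 in resting cells at 16 h, and 0.848 for Rps23 in resting cells at 2 h. For the chemokine list's median it was 0.847 in activated cells at 2 h and 0.849 at 16 h.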

How the results depend on the processing

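The fit without 3 arrays of resting cells was chosen after the data were seen, and all other settings before. Gene counts follow the order resting 2 h, activated 2 h, resting 16 h, activated 16 h, then the differences in response between activated and resting cells at 2 h and at 16 h and between 16 h and 2 h in resting and in activated cells, then the antigen effects at 2 h, at 16 h and between the times. An adjusted p under 0.01 in place of 0.05 gave 1045, 3674, 1532, 3327, 483, 639, 21 and 1746 genes, and 1169 for antigen at 16 h, which its stricter threshold explains by construction. Centring arrays on their median gave 10464, 11045, 12469 and 13517 genes in the 4 groups, 2214 for the difference at 16 h, and 302 and 5343 for the differences over time in resting and activated cells. By construction it leaves in the intensity-dependent trend that loess removes. Fitting only the groups compared gave 375 genes in resting cells at 2 h, 1729 at 16 h, 571 for the difference at 2 h and 8 for the difference over time in resting cells. Without the 3 arrays the counts were 523 in resting cells at 16 h, 641 for the difference at 16 h, 7 for the difference over time in resting cells and 1234 for antigen at 16 h. The difference over time in resting cells (49 genes) also moved to 19 with Agilent's processed signals, 19 with the authors' value table, 77 with no background correction and 29 with slide as a block. For antigen at 16 h the Cy5 channel gave 3288 genes. For changes other than those named as set by construction, the cause was not tested.

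With the replicate block the difference over time in resting cells held 275 genes in place of 49. The block ended 3 list calls and added 10, each given beside its result. It changed no other list call, and 503 of 503 values of named genes kept direction and side of the threshold.

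Leaving out each array in turn gave 1263 to 2058 genes in resting cells at 2 h, 3866 to 5054 in activated cells at 2 h, 1452 to 3651 in resting cells at 16 h and 3522 to 4342 in activated cells at 16 h. The differences gave 576 to 1097 (2 h), 862 to 1686 (16 h), 23 to 1959 (resting cells over time) and 2209 to 2708 (activated cells over time). Antigen effects gave 6708 to 7224, 1589 to 1935 and 5175 to 5740. Of 3502 values of named genes 3374 kept their direction and side of the threshold, 126 fell below it and 1 passed it.

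Under median centring 322 of 358 values of named genes kept direction and side, 23 lost their call, 2 gained one and 11 changed sign. The sign changes in resting cells at 2 h were Aurka (0.17), Itga2b (0.00443), Mcm6 (0.32), Mcm7 (0.16) and Tyms (0.25), and at 16 h Havcr2 (0.33) and Rab5c (0.0175). In activated cells they were Gsdme (0.0795) at 2 h and Egr1 (0.0672), Ier2 (0.0414) and Lyz2 (0.14) at 16 h. Aurka, Itga2b, Mcm7, Rab5c, Gsdme, Egr1, Ier2 and Lyz2 still lay below the shifted median gene, and Mcm6, Tyms and Havcr2 above it. Lists that turned were cytokines (adjusted p = 0.398), Fc-epsilon-RI signalling (0.00584), cell cycle (0.321), unfolded protein response (0.0225) and lymphocyte markers (0.0225) in resting cells at 2 h, cytokines at 16 h (0.00475), and lymphocyte markers in activated cells at 16 h (0.0124). With the strict filter eicosanoid genes turned in the difference over time in activated cells (0.0236). Averaging a gene's probes turned Tph1 in activated cells at 2 h (-0.00827) and Hk1 at 16 h (-0.00686), and the Cy5 channel (anti-TIM-3-treated cells) turned Csf1 for antigen at 16 h (-0.18). The causes were not tested.

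The anti-TIM-3 medians of genes changed by antigen, given for ratios of replicates 3 and 4 and then of 1 and 2, moved as follows. Median centring gave 0.47 and 0.48 for genes raised at 2 h, 0.17 and 0.19 for genes lowered at 2 h, which changed sign, 0.56 and 0.59 for genes raised at 16 h, and 0.62 and 0.64 for genes lowered then. Agilent's processed signals and the authors' value table each gave -0.16 and -0.16 for genes lowered at 2 h. Antigen calls from Cy5 contain the effect of anti-TIM-3, which by construction puts genes it raises among those raised, and gave -0.11 and -0.12 for genes lowered at 2 h, 0.17 for genes raised at 2 h (replicates 1 and 2), 0.24 and 0.30 for genes raised at 16 h, and -0.12 and -0.21 for genes lowered at 16 h, which changed sign. The separate-channel model gave 0.11 for genes lowered at 16 h (replicates 3 and 4). For changes other than those with calls from Cy5 the cause was not tested.

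An estimated correlation left 40 of the 103 list calls. Lost were 13 of 77 list calls with Agilent's processed signals, the authors' value table and median centring each (25 gained with the last), 6 of 26 in the Cy5 channel and 8 of 95 with only the groups compared. Of the 103, averaged probes and the fit without the 3 arrays ended 9 each, the strict filter 8 and slide as a block 5, and no filter added 15. The causes were not tested. List calls printed above with 1 adjusted p alone held under it. Of named gene values, 323 of 358 stayed with Agilent's processed signals (34 lost their call), 423 of 464 with only the groups compared (41 lost), 457 of 503 without the 3 arrays (46 lost), 490 of 503 with slide as a block (13 lost), 488 of 503 with averaged probes, 499 with no filter and 140 of 145 in the Cy5 channel. No background correction (502), an offset of 16 (500), the strict filter (474 of 474), quantile normalization (145 of 145) and the separate-channel model (143 of 143) moved at most 3. Changes of genes near background are bounded or understated.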

Other observations

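The lists and genes below were chosen after their values were seen, and no hypothesis about them was tested.

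Interferon response and macrophage genes stood at different levels by replicate number in IgG-treated cells. Averaged over the 4 groups, the mean log2 Cy3 level of the interferon list was 10.7 for replicate 1, 9.24 for replicate 2, 9.50 for replicate 3 and 9.81 for replicate 4. Single arrays of replicate 1 ranged from 10.5 to 11.1 and those of replicate 2 from 8.97 to 9.49. Macrophage and dendritic cell markers stood at 10.2, 9.04, 9.57 and 9.98. Cell cycle genes, which differ between resting and activated cells, were at 11.3, 11.2, 11.2 and 11.1. Within a spot the channels' residuals correlated at 0.534 in the separate-channel model.

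For a few genes a probe other than the tested one passed the threshold in the opposite direction. Klc1, a kinesin light chain, was at -0.61 in activated cells at 2 h and its other probe at 0.19. Csf2rb, the shared receptor subunit for IL-3, IL-5 and GM-CSF, was at 1.09 in resting cells at 16 h, and its other probes at -0.25 and -0.11. Klf2, a zinc-finger transcription factor, was at 0.57 there and its other probe at -0.39. Alox5 was at 0.38 in activated cells at 2 h, with other probes at -0.20 and 0.22. The death receptor gene Fas differed over time in activated cells by 0.34 on one probe and -0.18 on another. The metallothionein gene Mt1 differed between cell states at 16 h by 0.17 and -0.31.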
